A study of Mus musculus with 6 samples.

How the data were processed

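RNA was measured in 6 libraries of mouse fetal liver, 3 from the group labelled NC and 3 from the group labelled miR-29a-3p. Per the labels' protocols, RNA was extracted with Trizol and made into libraries with the Illumina TruSeq RNA Sample Prep Kit from total RNA. The labels do not say whether the libraries came from separate dams or separate fetuses, so p-values here measure only the spread between these samples, which may in part be technical. Groups and replicate numbers were taken from the sample titles, and every sample had a group.

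The authors deposited 1 table of normalized expression values with 14423 genes and a column for each library. The deposited table names no unit, and the values were identified as FPKM, fragments or reads per kilobase of gene and per read total of the library, from their own structure. Multiplied by the gene's merged exon length in GENCODE release M21, values were whole multiples of 1 step per library. For 13314 genes, 92.4% of the 14413 with a length, this gave whole read numbers within a tolerance of 0.05 in all 6 libraries. The library totals that the steps imply were 16692223 to 18863730 reads. Counts themselves were not used as the main values, since they are read back only for genes whose length matched.

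Bowtie 0.12.2 and the build mm8 are named per the submitters' processing notes, with no role given for either. The gene coordinates in the deposited table point to a later build, since 13527 genes, 93.8%, had exactly the coordinates of GENCODE M21, an annotation of GRCm38. Coordinates below are therefore given as in the table, as GRCm38 positions. The read counter, the annotation release and the filter that chose the listed genes are not given in the sources used here. Every listed gene reached at least 0.518 FPKM in some library. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies carry uncertain values.

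Differential expression was computed with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and robust empirical Bayes moderation. Group was the only term. Genes with an FPKM of at least 1 in at least 3 libraries entered, which left 12158. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are miR-29a-3p over NC. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. The design written before the data were examined named a count model first and this limma test as its replacement should the table hold FPKM, and the replacement was used. Group means are given as FPKM ± SD, and fold changes ± their standard error. Reading used Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

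Before the data were examined, 44 gene lists were fixed. They covered glucose, lipid and amino acid metabolism, published miR-29 targets, the cell types of fetal liver and of neighbouring organs, cell states, RNA quality and sex. Of the 1003 listed genes, 884 were in the table, and the others were not analysed here. The 40 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 40 lists. Camera with an estimated correlation, camera on ranks and fry were run beside it. The lists for primitive erythroid cells, for muscle, for kidney, adrenal and lung, and for placenta had fewer than 3 tested members and were not tested. Called members are counted over all genes tested and adjusted over the list alone.

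Genes are named by a rule fixed before the data were examined. It takes the 12 called genes with the largest fold change in each direction, with a mean of at least 2 FPKM, a standard symbol and no overlap between the groups. It adds 39 genes fixed by name, of which Pik3r3 and Tet1 were not analysed here, and up to 4 called members of each list, or up to 2 members called over the list alone where none passed. The called list members Sds, Klf15, Hgd, Grb10, Grb14, Sesn1, Fads2, Vnn1, Atf3 and Hsph1, and the pancreatic genes given by library, fall outside the rule and were chosen after their values were seen, as were the genes that open the closing observations. Some genes that the rule takes are not reported here.

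Matches to the miR-29 seed, TGGTGCT, were searched in the 3′ UTR of the protein-coding transcript with the longest 3′ UTR of each gene, in GENCODE M21. The 1672 tested genes with a match were compared with 8903 genes that had neither this match nor GGTGCTA. The difference of medians was given a 95% bootstrap interval from 2000 draws and compared with 20 shuffled seeds over genes of matched 3′ UTR length.

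The test was first run on simulated reads with the means and depths of the real libraries, a single spread for all genes taken from the replicates, and a set of genes changed by known amounts. For miR-29a-3p against NC over 11971 genes, it recovered 77.3% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 98.5% of those changed 4-fold. Of its calls, 4.76% were genes that had not been changed. The simulated genes varied independently of each other, so these shares may not hold for the real libraries, in which genes vary together.

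The alternatives were pseudocounts of 0.1 and 5, no filter and an FPKM of at least 5, and quantile, median-ratio and upper-quartile scaling. Further ones left out blood-cell genes, added a replicate block, ran limma's voom on the recovered reads of 11148 genes with and without library weights, or left out each library in turn. The threshold and the list test were also varied. Ranges of adjusted p over the alternatives leave out the settings that change only the threshold or the fold tested against. Upper-quartile scaling of FPKM and a fit without the 2 libraries richest in pancreatic enzymes were chosen after seeing the data. The alternatives that were to use a count table were not run, and voom was the only model fitted to the recovered reads. Replicates were compared on the recovered reads before averaging, and none agreed within sampling noise: chi-square per degree of freedom was 9.94 to 39.0 within groups.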

Results

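Fetal liver RNA was profiled in 6 mouse libraries from pregnancies in which the dams, kept on a normal diet, were injected with extracellular vesicles, membrane-bound particles that carry RNA between cells. Injections were daily from gestational day 12.5, 6 in all. The vesicles were rich in the microRNA miR-29a-3p in 3 libraries and rich in the control named NC in the other 3. The series names glucose metabolism of the fetal liver as its question. Its title speaks of rat, while the labels and the gene identifiers are those of mouse. Read totals recovered from the FPKM values were 16692223 to 18863730 per library, and 11663 to 12203 genes per library reached an FPKM of 1. Albumin alone made up 10.5% to 12.1% of the summed FPKM. Log2 values correlated across genes at 0.976 to 0.989 within groups and at 0.957 to 0.978 between them, genes not being independent replicates. The first principal component held 46.2% of the variance and placed the NC libraries at -21.06 to -14.37 and the miR-29a-3p libraries at 9.86 to 27.88.

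In the miR-29a-3p livers, Pck1 (ENSMUSG00000027513; chromosome 2, 173153048 to 173159273), which encodes the cytosolic enzyme that commits carbon to gluconeogenesis, rose from 5.32 ± 1.89 FPKM in NC to 198.5 ± 121.5 (SD, n = 3 each), a ratio of means of 37.3. Tat, the tyrosine aminotransferase of amino acid breakdown, rose from 5.81 ± 3.41 to 81.2 ± 27.6 FPKM, and the histone methyltransferase gene Setdb2 from 3.13 ± 0.63 to 37.0 ± 11.3 FPKM. Txnip, which restrains glucose uptake, rose from 63.9 ± 9.8 to 287.7 ± 9.6 FPKM, and Pdk4, which inhibits pyruvate dehydrogenase, from 22.6 ± 1.0 to 77.9 ± 28.9 FPKM. Their log2 fold changes were 4.83 ± 0.45, 3.66 ± 0.36, 3.17 ± 0.21, 2.16 ± 0.12 and 1.68 ± 0.22 in this order, with limma's Benjamini-Hochberg adjusted p (used for single genes throughout) between 0.0014 for Txnip and 0.0147 for Pdk4. The kinase gene Sgk1, the phosphatidate phosphatase gene Lpin1, Igfbp1, which encodes a binding protein of insulin-like growth factors, Gadd45b, Slco4c1 and Phf11c were also among the 12 largest increases, with Slco4c1 at 2.52 ± 1.83 and 12.8 ± 0.6 FPKM and Gadd45b at 9.42 ± 1.00 and 33.0 ± 10.2 FPKM. Another annotated gene lies within Setdb2, so reads of the pair cannot be told apart.

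Among the 12 largest decreases, Egln3 (ENSMUSG00000035105; chromosome 12, 54178981 to 54203860), an oxygen-sensing prolyl hydroxylase gene, fell from 40.3 ± 7.3 to 11.8 ± 3.1 FPKM. Angptl8, a feeding-induced regulator of lipoprotein lipase, fell from 44.0 ± 12.5 to 11.1 ± 3.9 FPKM, and G0s2, an inhibitor of triglyceride lipase, from 196.2 ± 51.4 to 68.1 ± 21.1 FPKM. The log2 fold changes were -1.71 ± 0.19 for Egln3, -1.91 ± 0.30 for Angptl8 and -1.53 ± 0.27 for G0s2, at limma's adjusted p of 0.0094, 0.0258 and 0.032. Cpm, with the largest fall on the log2(FPKM + 1) scale of -2.01 ± 0.39, Aox3, Hsd3b6, Abca8a, Rtl3, Plin4, Phlda1 and the mitochondrial ribosomal RNA mt-Rnr1, at -1.46 ± 0.21, also belonged to these 12. By ratio of mean FPKM, Plin4 fell further than Cpm, 5.34-fold against 4.31-fold. Hsd3b6 and mt-Rnr1 have near-identical copies elsewhere in the genome, so their values are uncertain.

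Over 12158 genes tested, 202 were higher and 284 lower in miR-29a-3p than in NC at limma's adjusted p under 0.05, and in all 486 the 3 values of one group lay outside those of the other. Of these, 58 were higher and 48 lower by at least 2-fold. At an unadjusted p under 0.05, 1118 were higher and 1615 lower, and the groups did not overlap in 29.5% of tested genes against the 10% that chance gives. That 10% is a mean over all splits of the libraries, and since genes vary together a single split can lie far from it. The share in splits that mix the groups was not analysed here. The counts depended on single libraries: they were 90 and 95 without NC 1, 23 and 11 without NC 2, 16 and 9 without NC 3, and 86 and 90 without miR-29a-3p 2. In every such fit 21 genes stayed called, among them Pck1, Tat, Setdb2, Txnip, Sgk1, Phf11c, Bcl2l11, Lpin2, Pfkfb3, Phlda1, Abca8a, Hsd3b6, Cirbp and Cry2, and every other gene named as risen or fallen was not called in at least 1 of the 6 fits.

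**Figure D1:**
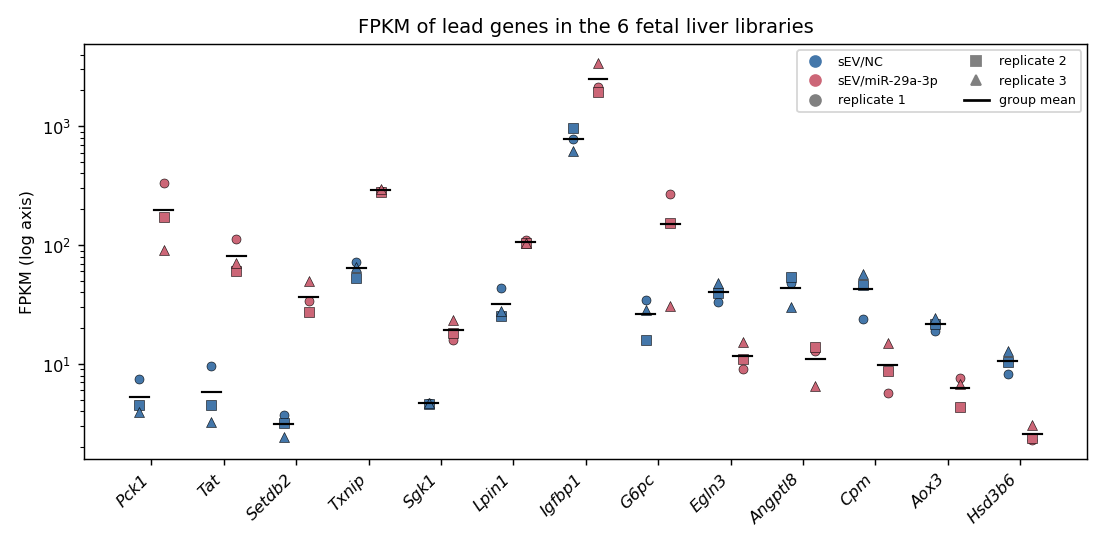
FPKM on a log axis for 13 genes in the 3 NC and 3 miR-29a-3p libraries, each point a library and each bar a group mean. Pck1 had a mean of 5.32 FPKM in NC and 198.5 FPKM in miR-29a-3p, while G6pc, which did not pass the test, had overlapping groups.

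Of 23 tested gluconeogenesis genes, 6 rose, none fell and 17 did not pass, and 7 passed adjusted over the list alone. Besides Pck1 and Tat these were Ppargc1a, a coactivator of the gluconeogenic programme, from 2.77 ± 0.61 to 6.04 ± 0.53 FPKM, Slc37a4, the glucose-6-phosphate transporter gene, from 84.9 ± 2.3 to 124.1 ± 3.7 FPKM, the serine dehydratase gene Sds and the transcription factor gene Klf15. Ppargc1a had a log2 fold change of 0.91 ± 0.13 and Slc37a4 one of 0.54 ± 0.08, both at limma's adjusted p of 0.0174. G6pc, the catalytic subunit of glucose-6-phosphatase, measured 34.5, 15.9 and 28.6 FPKM in NC 1 to 3 and 268.0, 154.7 and 30.8 FPKM in miR-29a-3p 1 to 3. Its log2 fold change of 2.08 ± 0.82 did not pass (adjusted p = 0.216), and without miR-29a-3p 3 it was 2.97 with an adjusted p of 0.0292 (range over the alternatives 0.0292 to 0.426). Fbp1 and Pcx, enzymes of the same pathway, did not pass, at -0.18 ± 0.08 and 0.06 ± 0.09. The list's median was 0.14 and camera's adjusted p was 0.0058 (adjusted p = 0.971 with an estimated correlation). The call also ended with camera on ranks (adjusted p = 0.0515) and with fry (adjusted p = 0.0606), with a range over the alternatives of 0.0016 to 0.971. Camera called 7 of 40 lists in all, none of them with an estimated correlation. Splits of the libraries that mix the groups called 5 to 16, most of them more than 7.

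Amino acid breakdown genes moved both ways. Of 24 tested urea cycle and amino acid catabolism genes, 5 rose, 1 fell and 18 did not pass, with 8 higher and 1 lower adjusted over the list alone. Among the 5 were Tat and Sds, which belong to both lists and were counted above with the gluconeogenesis genes. Mat1a, which makes the methyl donor S-adenosylmethionine, rose from 250.6 ± 92.7 to 575.2 ± 70.8 FPKM, the proline dehydrogenase gene Prodh from 2.01 ± 0.43 to 4.15 ± 0.31 FPKM and the urea cycle gene Asl from 36.0 ± 2.3 to 55.8 ± 6.1 FPKM, while Hgd, a later step of tyrosine breakdown than Tat, was the member that fell. The list's median of -0.04 and mean of 0.24 differed in sign, and camera did not call it (adjusted p = 0.23).

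Of 23 tested glycogen genes, 4 fell, none rose and 19 did not pass, and 9 were lower and 1 higher adjusted over the list alone. Ppp1r3b, which targets a phosphatase to glycogen, fell from 36.6 ± 3.5 to 18.9 ± 5.8 FPKM, the liver phosphorylase gene Pygl from 86.6 ± 0.7 to 62.6 ± 4.0 FPKM and the glycogen-binding gene Stbd1 from 43.2 ± 5.4 to 28.8 ± 3.0 FPKM. Pygl acts in breakdown and Ppp1r3b in synthesis. Gys2, the liver glycogen synthase gene, stood at 88.8 ± 23.8 and 63.4 ± 20.9 FPKM and did not pass (adjusted p = 0.322, with a range over the alternatives of 0.0460 to 0.605). The median of the list was -0.29 and camera's adjusted p was 0.0428 (adjusted p = 0.742 with an estimated correlation), a call that also ended without NC 2 (adjusted p = 0.0603), miR-29a-3p 1 (0.08335) or miR-29a-3p 2 (0.06867), with a range over the alternatives of 0.0040 to 0.742.

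Among 29 tested glycolysis genes 2 fell, 1 rose and 26 did not pass, with 6 lower and 2 higher adjusted over the list alone. Pfkfb3, which makes the activator of phosphofructokinase, fell from 8.53 ± 0.46 to 3.46 ± 0.51 FPKM at a log2 fold change of -1.10 ± 0.11, and Slc16a1, the monocarboxylate transporter gene and a published miR-29 target, from 61.3 ± 3.7 to 42.6 ± 3.4 FPKM at -0.52 ± 0.10. Limma's adjusted p was 0.0068 and 0.0326. Pklr did not pass, at -0.31 ± 0.19. Camera gave the list a median of -0.28 and an adjusted p of 0.0494 (adjusted p = 0.991 with an estimated correlation), and the call ended without NC 2 (0.0603), NC 3 (0.122), miR-29a-3p 1 (0.301) or miR-29a-3p 2 (0.0643), with a range over the alternatives of 0.0012 to 0.991. Neither the 33 genes of pyruvate dehydrogenase and the citrate cycle (adjusted p = 0.739), in which Pdk4 alone passed, also adjusted over the list alone, nor the 10 of the pentose phosphate pathway (0.941) nor the 6 glucose transporters (0.881) were called, and Slc2a2, the main transporter of liver, stood at -0.15 ± 0.10.

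Insulin and insulin-like growth factor signalling held 4 higher and 4 lower genes among 39 tested, with 31 not past the threshold, and 4 higher and 6 lower adjusted over the list alone. Igfbp1 rose from 786.2 ± 168.3 to 2489 ± 798 FPKM, a log2 fold change of 1.64 ± 0.24, and the stress-responsive genes Sesn1, Sesn2 and Trib3 rose with it. Irs1, an adaptor of the insulin receptor, fell from 2.62 ± 0.19 to 1.15 ± 0.04 FPKM, Igfals from 10.7 ± 1.0 to 5.77 ± 0.77 FPKM, and the receptor-binding adaptors Grb10 and Grb14 by less than a log2 unit. Insr, Irs2, Igf1, Akt2, Foxo1 and Pik3r1 did not pass, with log2 fold changes between -0.15 for Foxo1 and 0.14 for Irs2. Igf2 stood at -0.52 ± 0.13 (adjusted p = 0.064, and 0.0323 without miR-29a-3p 1, with a range over the alternatives of 0.0094 to 0.22), and its exons overlap those of another annotated gene, so its level is uncertain. The list was not called by camera (adjusted p = 0.557). Pik3r3 was not analysed here.

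Lipid genes also split. In fatty acid and triglyceride synthesis, 27 genes tested, Lpin1 rose from 32.3 ± 9.6 to 105.7 ± 3.6 FPKM and Lpin2 from 15.5 ± 0.6 to 32.7 ± 3.4 FPKM, while the elongase gene Elovl6 fell from 29.8 ± 1.2 to 16.2 ± 1.3 FPKM, the desaturase gene Scd2 from 87.1 ± 24.1 to 32.7 ± 8.6 FPKM and the desaturase gene Fads2 from 50.7 ± 15.5 to 21.4 ± 4.5 FPKM. Adjusted over the list alone 3 were higher and 9 lower. Of 35 tested genes of fatty acid oxidation and ketogenesis, Angptl4 and Eci2 rose and Fabp1, Acadm and Vnn1 fell, and 2 were higher and 4 lower adjusted over the list alone. Fabp1, the fatty acid binding protein gene of liver, went from 443.6 ± 51.0 to 223.9 ± 55.2 FPKM. None of 24 cholesterol synthesis genes passed in limma, 1 higher and 6 lower at an unadjusted p under 0.05, none by voom, 1 lower by voom with library weights and none adjusted over the list alone. Camera called none of these lists (adjusted p = 0.083 for synthesis, 0.101 for oxidation and 0.083 for cholesterol). Without NC 3 it called synthesis (0.0068) and cholesterol (6.54e-04), and without miR-29a-3p 2 cholesterol (0.0043). Quantile normalization gave calls for all 3 lists (0.03004 each) and median-ratio scaling for synthesis and cholesterol (0.0404 each), all lower. Over the alternatives the adjusted p ran from 0.0068 to 0.991 for synthesis, from 0.03004 to 0.991 for oxidation and from 6.54e-04 to 0.991 for cholesterol.

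Hypoxia-induced genes lay mostly lower, with 4 of 15 fallen, none risen and 11 not past the threshold, and 7 lower adjusted over the list alone. With Egln3 and Pfkfb3, Egln1 fell from 20.4 ± 2.5 to 12.1 ± 2.2 FPKM and P4ha1 from 7.11 ± 0.75 to 4.01 ± 0.84 FPKM. The median was -0.25 and camera's adjusted p was 0.0041 (adjusted p = 0.991 with an estimated correlation), and 0.08335 without miR-29a-3p 1 (range over the alternatives 9.13e-06 to 0.991). Immediate early and heat shock genes went both ways, 4 higher and 2 lower of 20, with 8 higher and 4 lower adjusted over the list alone. Zfp36, which encodes an mRNA decay factor, rose from 19.04 ± 0.84 to 35.8 ± 5.7 FPKM, and Dusp1, Jund and Atf3 also rose, while Junb fell from 18.3 ± 3.2 to 9.03 ± 0.93 FPKM and the chaperone gene Hsph1 from 2.81 ± 0.75 to 1.33 ± 0.19 FPKM. Camera's adjusted p for this list was 0.028 (adjusted p = 0.742 with an estimated correlation), and 0.054 without NC 2 (range over the alternatives 0.0050 to 0.742). All 43 ribosomal protein genes had fold changes above 0, with a median of 0.19 and a camera adjusted p of 1.17e-08 (adjusted p = 0.991 with an estimated correlation), yet none passed singly in limma, 16 being higher at an unadjusted p under 0.05, none called by voom, 5 higher by voom with library weights and none adjusted over the list alone.

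**Figure D2:**
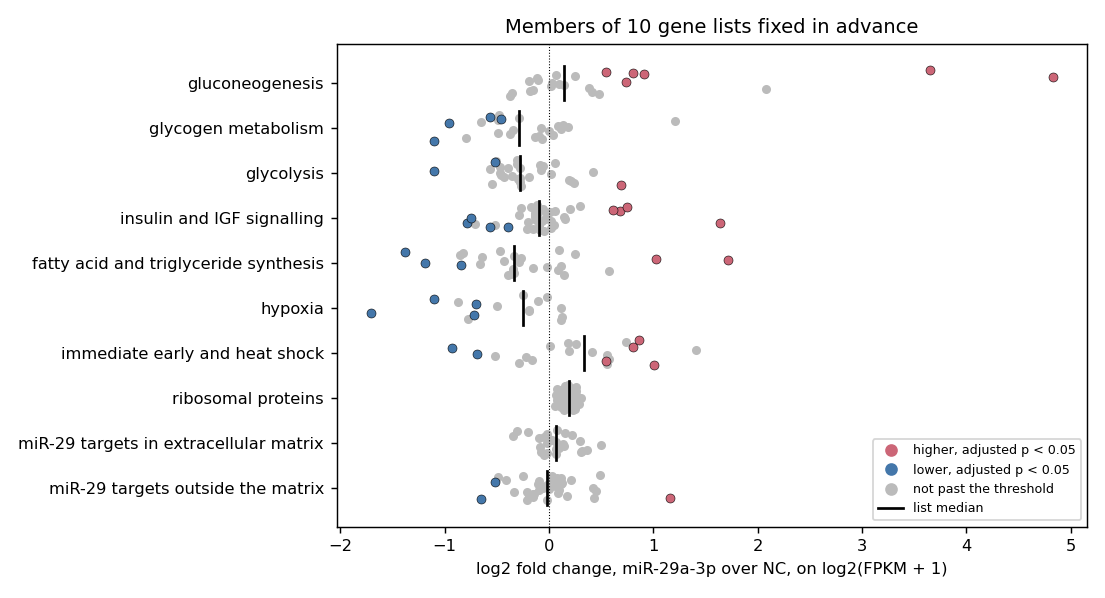
Log2 fold changes of miR-29a-3p over NC for the tested members of 10 gene lists, each point a gene, coloured where it passed an adjusted p under 0.05, with a bar at the list median. The 6 called gluconeogenesis genes lie to the right and the 4 called glycogen genes to the left of 0.

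Published targets of miR-29 showed no shift past the test in either list. None of the 27 tested targets in extracellular matrix passed in limma, and 2 were lower and none higher at an unadjusted p under 0.05, with none called by voom, 1 lower by voom with library weights and none adjusted over the list alone. Col1a1 stood at 27.2 ± 6.5 and 34.4 ± 12.2 FPKM, Col3a1 at 21.8 ± 3.4 and 29.02 ± 9.70 FPKM, and Col1a2, Col4a1, Col4a2, Fbn1, Eln and Sparc had log2 fold changes between 0.06 for Col4a1 and 0.32 for Col1a2. The median was 0.06 (camera adjusted p = 0.649). Of 39 targets outside the matrix, Slc16a1 and Bace1, the beta-secretase gene, fell and the apoptosis gene Bcl2l11 rose, from 2.68 ± 0.13 to 7.25 ± 1.00 FPKM, with 2 lower and 3 higher adjusted over the list alone and a median of -0.02 (camera adjusted p = 0.941), which became 0.009 under median-ratio scaling. The DNA methyltransferase genes Dnmt3a, at -0.33 ± 0.09 (adjusted p = 0.0946, and 0.047 by voom, with a range over the alternatives of 0.0129 to 0.289), and Dnmt3b, at -0.21 ± 0.13, did not pass, nor did Tet2, Tet3, Mcl1 and Insig1. Tet1 was not analysed here. Of 32 matrix genes not listed as targets 1 passed, Lama1, which fell, and none adjusted over the list alone (camera adjusted p = 0.274).

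Across the transcriptome, the 1672 tested genes with a miR-29 seed match in the 3′ UTR had a median log2 fold change of -0.022, against -0.025 for the 8903 without. The difference of 0.0036 had a 95% bootstrap interval of -0.0117 to 0.0173, and limma's camera did not call the set. Over genes of matched 3′ UTR length the difference was 0.0188, and 19 of 20 shuffled seeds lay below it, in a range of -0.0090 to 0.0232. Of the 252 genes that fell and had a 3′ UTR, 13.9% carried a match (95% exact interval 9.87% to 18.8%), against 14.9% in length-matched draws (one-sided p = 0.71 by simulation over 10000 draws). The level of the microRNA itself in liver was not analysed here.

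**Figure D3:**
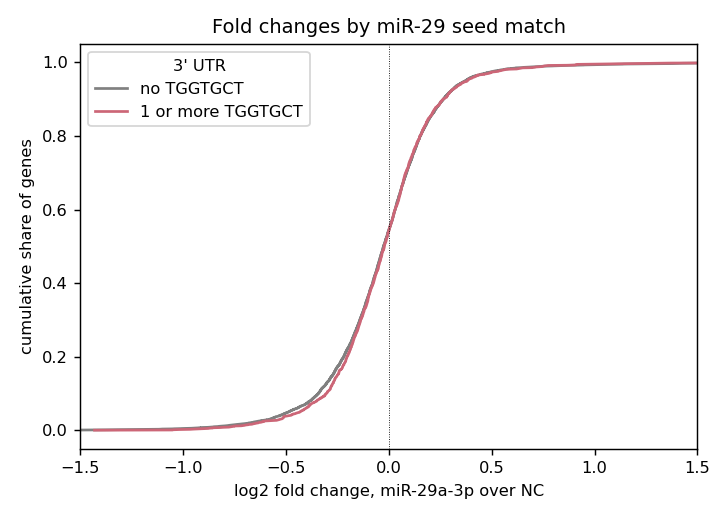
Cumulative share of genes by log2 fold change of miR-29a-3p over NC, for the 1672 protein-coding genes with a TGGTGCT match in the 3′ UTR and for the remaining genes with a 3′ UTR and no such match. The curves overlap closely, and the median of the genes with a match was -0.02.

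Marker lists of cell types held few called genes. Albumin stood at 45910 ± 602 and 44240 ± 2618 FPKM, Afp at 7290 ± 1070 and 7369 ± 1670 FPKM, and the adult globin gene Hbb-bs at 15470 ± 773 and 17660 ± 2995 FPKM, none of them past the threshold. Of 30 hepatocyte secreted protein genes Apoc3 alone passed, falling from 67.4 ± 3.9 to 37.4 ± 3.5 FPKM, and of 27 definitive erythroid genes the erythroid transcription factor gene Klf1 alone, falling from 101.6 ± 16.9 to 64.6 ± 8.0 FPKM. In the acute phase list Il1r1 rose and Steap4 fell, in the stress list Ddit4, Sesn2 and Trib3 rose and Psat1 fell, and among hepatic cytochromes and xenobiotic enzymes Cyp3a11 and Cyp3a13 rose and Ugt2b5 fell. Adjusted over the list alone, 1 secreted protein gene was lower, no erythroid gene passed, 1 acute phase gene was higher and 1 lower, 4 stress genes were higher and 5 lower, and 3 cytochrome and enzyme genes were higher and 6 lower. Camera called none of these lists (adjusted p between 0.421 and 0.881), though without miR-29a-3p 1 it called the erythroid list (0.0366, range over the alternatives 0.0153 to 0.996). The near-identical Cyp3a, Ugt2b and globin genes carry uncertain values.

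The 23 lists with no called gene in limma held 392 genes, of which 37 were higher and 32 lower at an unadjusted p under 0.05, and voom called 2 higher and 3 lower, voom with library weights 10 higher and 15 lower. They were the hepatoblast, blood progenitor, granulocyte, macrophage, megakaryocyte, mast cell, lymphoid, endothelial, stellate, cholangiocyte, mesothelium, pancreas, intestine, proliferation, interferon, ribosomal, mitochondrial, oxidative phosphorylation, pentose phosphate, glucose transporter, cholesterol, matrix target and sex-linked lists. Adjusted over the list alone, Sox9 in the cholangiocyte list, Vil1 in the intestine list and Igf2 in the hepatoblast list were lower and no other member of the 23 lists passed. Apart from the ribosomal and pancreas lists, camera called none of them, with adjusted p between 0.083 and 0.982. Leaving out 1 library gave calls for the endothelial list (0.0153 without NC 2 and 0.0040 without miR-29a-3p 2), the megakaryocyte list (0.0412 without NC 1 and 0.0043 without miR-29a-3p 2), the mast cell list (0.0107 without miR-29a-3p 2), proliferation (2.37e-04 without miR-29a-3p 1) and the mitochondrial transcripts (0.0482 without NC 3 and 0.0298 without miR-29a-3p 2), the last also with quantile normalization (0.03004). Over all alternatives the adjusted p of each of these ran from the lowest value given here to 0.991. Median, mean and test differed in sign for the erythroid, glucose transporter, intestine and cholangiocyte lists and for the miR-29 targets outside the matrix, each with a median within 0.1 of 0. The medians of the glucose transporter, oxidative phosphorylation, cholangiocyte, stellate and hepatocyte secreted lists changed sign under another scaling, and those of the acute phase, interferon, intestine and cholangiocyte lists by voom with or without library weights.

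Pancreatic enzyme transcripts differed widely between libraries of the same group. Ctrb1, a chymotrypsinogen gene, measured 54.6, 51.3 and 1.02 FPKM in NC 1 to 3 and 299.1, 0.77 and 330.9 FPKM in miR-29a-3p 1 to 3, and Clps, Cela2a, Cel, Cpa1 and Prss2 varied in step. None of 10 tested pancreas genes passed in limma, adjusted over the list alone, at an unadjusted p under 0.05 or by voom with or without library weights. Camera's adjusted p for the list was 0.0494 (adjusted p = 0.991 with an estimated correlation), and 0.196, 0.237 and 0.422 without NC 3, miR-29a-3p 1 and miR-29a-3p 3 (range over the alternatives 3.22e-11 to 0.991). The list's median was 1.48 and turned to -1.073 by voom with library weights. Without miR-29a-3p 1 and 3, the libraries richest in these enzymes, 26 genes were higher and 43 lower, a count chosen after seeing the data in which the single miR-29a-3p library left is assumed to vary like the NC ones.

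**Figure D4:**
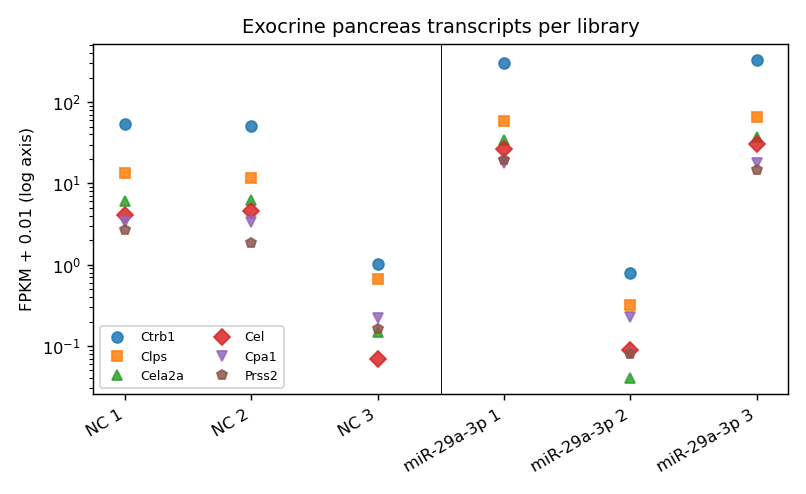
FPKM plus 0.01, on a log axis, of 6 exocrine pancreas genes in each of the 6 libraries. Ctrb1 was at 51.3 FPKM or more in NC 1, NC 2, miR-29a-3p 1 and miR-29a-3p 3, and at 1.02 and 0.77 FPKM in NC 3 and miR-29a-3p 2.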

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

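Upper-quartile scaling and the fit without the 2 libraries richest in pancreatic enzymes were chosen after seeing the data. Every call kept its direction in each alternative that tested the gene. For the fits that left out libraries or changed the pseudocount, filter, block or threshold this was set beforehand, since the groups did not overlap in any of the 486 called genes. Of 2021 values of named genes under alternatives, 1674 stayed on their side of the threshold, 332 lost and 15 gained a call, and 39 of the 1674, called neither as reported nor in the alternative, changed sign. Of 825 list values, 755 stayed on their side, 43 of these with a median of another sign and no call in either, 45 lost and 23 gained a call, and 2 changed direction with a call: the pancreas median was -1.073 by voom with library weights, and the interferon median 0.186 without the 2 libraries richest in pancreatic enzymes, where the list was called (adjusted p = 0.0239, with a range over the alternatives of 0.0239 to 0.991). That fit also called the granulocyte list lower (-0.22, adjusted p = 0.00499, range 0.00499 to 0.9997) and the erythroid and proliferation lists higher (0.0153 and 0.0219, ranges 0.0153 to 0.996 and 2.37e-04 to 0.991). For these and the changes below the cause was not tested. Leaving out 1 library gave 16 to 169 genes higher and 9 to 310 lower. Besides the fits named in the report, 169 and 310 were called without miR-29a-3p 1 and 143 and 201 without miR-29a-3p 3.

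Against 202 and 284, voom with library weights called 486 and 686, an adjusted p under 0.1 gave 450 and 691, an unadjusted p under 0.05 with a 2-fold change 71 and 69, a test against a 1.2-fold change 25 and 22, and the fit without the 2 libraries 26 and 43. The 7 lists became 4 with a pseudocount of 0.1, 4 with upper-quartile scaling, 3 with voom, 3 on ranks, 1 with fry and 0 with an estimated correlation. All other counts of genes, and the list counts without a library, stayed within 1.5 times. The difference between seed-site genes and others ranged from -0.0150 to 0.0188 over the alternatives and passed in none that had a test.

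Replicate numbers do not pair the samples by the labels, and deviations of same-numbered libraries correlated at 0.279, -0.303 and 0.055. With the number as a block, 202 genes were higher and 313 lower, of which 381 were among the 486 called without it. Of 65 named calls 58 were kept, and calls were gained by Gys2 (-0.49, adjusted p = 0.0460), Sox9 (-0.69, 0.0437), the cholesterol list (0.00187) and the fatty acid and triglyceride synthesis list (0.0114). The pancreas list without the 2 libraries had too few tested genes for a value. Count-model fits with TMM, RLE, upper-quartile or no factors, and a second count tool, were not run, and voom was the only model fitted to the recovered reads. Genes near 1 FPKM rest on fewer reads than others, which limits calls among them.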

Other observations

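The genes of this paragraph, and the tests of the glucocorticoid and FoxO lists, of the shared ratio of pancreatic transcripts and of the mitochondrial messenger RNAs below, were chosen only after the result was seen. Dusp1, Angptl4 and Irs2, whose values had been seen, were taken out of the glucocorticoid and FoxO lists after a first run that had met the same bound. The cold-inducible RNA-binding protein gene Cirbp rose from 6.80 ± 0.36 to 19.6 ± 2.2 FPKM and its relative Rbm3 from 31.5 ± 4.6 to 45.3 ± 0.9 FPKM (SD, n = 3 each), while the co-chaperone genes Stip1 and Chordc1 fell by 0.47 and 0.52 on the log2 scale. Setdb2 and its neighbour Phf11c on chromosome 14 rose together, by 3.17 and 1.77, while Phf11d and Rcbtb1 on the same side stood at -0.10 and -0.01 and did not pass, and Cab39l on the other side at 0.61 (limma, adjusted p = 0.0742). The pregnane X receptor gene Nr1i2 and Alas1, the first step of haem synthesis in liver, rose by 0.53 and 0.83, as did Cyp3a11 by 1.11. The pioneer factor genes Foxa1 and Foxa2 fell from 3.88 ± 0.19 to 2.09 ± 0.58 and from 10.8 ± 0.9 to 4.65 ± 1.69 FPKM. The clock genes Per1 and Cry2 rose by 0.95 and 1.21.

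The rise of Pck1, Tat, Igfbp1, Pdk4, Sgk1 and Lpin1 resembles a fasting or glucocorticoid response, a likeness that rests on these genes. It did not extend to the fatty acid oxidation and ketogenesis list, where 26 of 35 tested genes lay below 0 and 9 above. The median of that list was -0.155 (camera adjusted p = 0.101), with Angptl4 and Eci2 risen and Fabp1, Acadm and Vnn1 fallen. Of 18 glucocorticoid-responsive genes, the 16 tested had a median of 0.46, at percentile 100 of 10000 random lists matched on expression. Errfi1, Glul, Cebpd and Arl4d had risen and 12 were not past the threshold. Among those 12, Tgm2, Arrdc2 and Lcn2 lay below 0 with overlapping groups. Nfkbia, Sult1a1, Cdkn1a, Fkbp5 and Tsc22d3 lay above 0 without overlap, and Tob2, Mt2, Rhob and Mt1 above 0 with overlap. Of 16 FoxO targets, the 14 tested had a median of 0.20 at percentile 99.9, with Pik3ip1 and Ulk1 risen and 12 not past the threshold. Of these 12, Cat, Cited2, Ankrd46 and Sod2 lay below 0 with no overlap between the groups. Gabarapl1, Ccng2, Map1lc3b, Cdkn1b and Bnip3l lay above 0, also with no overlap, and Sirt1, Eif4ebp1 and Fbxo21 above 0 with overlap. Among all tested genes, 29.5% had no overlap. The random lists ignore correlation between genes, and the exocrine pancreas list, with no called gene, also reached percentile 100. These percentiles therefore cannot tell a group difference from genes that vary together. A difference in glucocorticoid exposure, in FoxO activity or in both may contribute and stays a hypothesis. A different hour of collection cannot be told apart from the groups: of 13 tested core clock genes, chosen without the already seen Per1 and Cry2 and with Tspan4, no clock gene, taken out after a first run in which it had not passed, 3 passed, Nr1d1 and Nr1d2 higher and Per2 lower, where at least 4 had been set as the mark of a shifted clock and at most 1 of an unshifted one, and the labels give no hour. Feeding of the dams and an effect of the injected vesicles stay open and were not tested.

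Direct repression of messenger RNA by miR-29 was tested as a source of the lower genes. It predicted an excess of seed matches among them, and the share was 13.9% (95% exact interval 9.87% to 18.8%) against 14.9% in length-matched draws. Of the 252 fallen genes, 217 were free of TGGTGCT, while GGTGCTA was not counted here. These values argue against direct repression as the source of the set. They do not for single genes that carry TGGTGCT, such as Slc16a1, Bace1 or Irs1, and say nothing of protein levels.

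Pancreatic enzymes in 4 of the 6 libraries may come from pancreatic tissue taken with the liver. The 17 exocrine genes mostly varied together, with a median pairwise r of 0.97 that rests on libraries at low, middle and high levels, and Spink1, at 38.2 to 59.4 FPKM throughout, did not follow (lowest pairwise r -0.36). Cela1 and Pnliprp1 were at 7.78 FPKM or more in every library, and expression of these genes by liver cells themselves was not tested. Whether such tissue contributes to the called genes cannot be told from these libraries: 100% of them kept at least 50% of their log2 fold change without the 2 richest libraries, but in all 486 called genes miR-29a-3p 2, as low in Ctrb1 as NC 3, already lay apart from NC, so the choice of genes set that share beforehand. Without the 2 libraries 26 genes were higher and 43 lower, 22 and 25 of them shared.

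The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 fell together, from 405.1 ± 93.3 to 147.9 ± 38.9 and from 211.9 ± 66.6 to 84.7 ± 20.1 FPKM. Less mitochondrial RNA altogether is argued against as the whole of this fall by the 13 mitochondrial messenger RNAs, with a median of -0.25 and quartiles of -0.281 and -0.105 against a mean of -1.38 for the ribosomal pair. All 13 lay below 0 (camera adjusted p = 0.0884, and 0.0482 without NC 3, 0.0298 without miR-29a-3p 2 and 0.03004 with quantile normalization, in a range of 0.0298 to 0.991), so a smaller common lowering stays open, and none passed singly in limma, with 1 lower at an unadjusted p under 0.05, none by voom and 1 lower by voom with library weights. A poorer yield of RNA without a poly(A) tail predicted lower values of 73 small nuclear, small nucleolar, small Cajal body and histone RNAs. Their median was 0.01 with quartiles of -0.29 and 0.38, with 3 called higher and none lower. This argues against a poorer yield of these 73 RNAs. It does not decide the question for the ribosomal pair, since reads of small RNAs that lie within other genes cannot be told apart from those genes. Processing or stability of the ribosomal transcripts, and reads shared with nuclear copies, stay open and were not tested.

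The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 202 genes higher and 284 lower, and the highest of the other splits 0 in limma. For the gene lists the real split called 7 and the others 5 to 16. Counting the real split, 7 of the 10 called as many lists as it or more. Lists were thus also called, at the preset correlation, where a split mixed the groups, mostly in larger number.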
